A study of Mus musculus with 2 samples.

How the data were processed

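Gene expression was measured in inguinal white adipose tissue, the subcutaneous fat depot of the groin, of male mice about 8 weeks old on chow at room temperature. Per the labels' protocols, total RNA was extracted with Trizol, RNA of 4 animals was pooled for each genotype, and each pool was labelled with biotin for 1 mouse gene array, so the series holds 1 wild-type (WT) array and 1 H4-TG array. What H4 stands for is not given in the sources used here. Because each group is 1 array on pooled RNA, there is no spread between replicates. No test for a difference between the genotypes was run and no p-value is given. Ranks of gene lists among random lists, given below, only describe these arrays. The number of arrays limits the precision of every value.

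The deposited value table holds a log2 signal for each of 35556 probes (transcript clusters) on both arrays. MAS5 is named in the submitters' processing notes; its version and settings, the summarisation of probes, and any scaling between the arrays are not given in the sources used here. The authors also deposited an analysed table of 869 probes with log2 bi-weight average signals of H4TG and CON, rounded, and a linear fold ratio of H4TG over CON, per the file headers. All 869 H4TG signals lay within 0.005 of the H4-TG column of the value table and all 869 CON signals within 0.005 of the WT column. In the authors' deposited table the lowest fold ratio was 1.50, so it lists only probes higher in H4-TG. Of the 1518 probes at least 1.5-fold higher in the value table, 849 stood in it and 669 did not, 452 of them among the lowest identifiers of the array, below 10344674, the lowest in the authors' table.

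The authors' table is the only source of gene names used here, so genes lower in H4-TG, and genes within 1.5-fold, are not named, and a gene missing from it has no value here. Of its rows, 822 carried 1 gene symbol and 47 several; the latter were not assigned to a gene. Symbols were brought up to date through mouse RefSeq genes of GRCm38: 746 rows matched by RefSeq accession, 46 by symbol, 10 by synonym and 20 not at all, and 58 rows received another symbol. These rows gave 800 genes, of which 14 had several probes and 4 had probes that differed by over 0.5 in their log2 difference; the brightest probe stood for the gene. The table's positions carry no genome build. Of 801 rows with a RefSeq gene, only 97 overlapped that gene in GRCm38, so positions are given as the table gives them.

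The value reported is the log2 signal of the H4-TG array minus that of the WT array, on the deposited scale. Probes counted had a mean of both arrays at or above the median over all probes, 6.31, and the size threshold was 2-fold. Before the data were examined, 33 gene lists with 672 distinct genes were fixed (adipocyte programmes, pathways and cell types that inguinal fat can hold), together with the rule for named genes: the 12 largest differences in each direction above the signal minimum, leaving out predicted, clone, small RNA, olfactory and vomeronasal receptor names; up to 4 members of each list above that minimum; and 10 genes always named, of which only Ucp1 stood in the authors' table. No gene could be named on the lower side. The plan was to give each list's median as its percentile among 10000 random lists over all measured genes. With names for the higher side alone, the random lists were drawn from the 800 named genes, matched on mean signal in 5 bins, for lists with at least 5 listed members. Such a median covers only members at or above about 1.5-fold and describes these arrays. Tested on simulated data with the 800 genes, a list of 25 raised by 1 on the log2 scale lay above all random lists. Of 20 lists not raised, 20 lay within the central range. The simulated differences were independent between genes and had no 1.5-fold limit, so this checks the calculation alone.

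The alternatives fixed beforehand were median centring, quantile normalization, no signal minimum, a minimum keeping the top 40% of probes, the mean over a gene's probes, the authors' analysed table, a 1.5-fold threshold and unmatched random lists. Centring along signal level (lowess, span 0.3) and leaving out the lowest identifiers were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 were used.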

Results

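The series compared inguinal white fat of H4-TG transgenic male mice with that of wild-type mice, with 1 array per genotype and RNA of 4 animals on each. The median log2 signal over 35556 probes was 6.34 on the WT array and 6.31 on the H4-TG array. Values are log2 signals on the deposited scale, differences are H4-TG minus WT, and none has a replicate check.

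Of the 33 gene lists fixed beforehand, 15 had no member in the authors' table and so no value. Only the thermogenic, matrix and skeletal muscle lists had at least 5 members there, and of these the skeletal muscle list had the highest median difference. All 25 members of the muscle list were in the authors' table of higher probes, 23 of them at least 2-fold higher, whereas 41 (6.34%) of the 647 list genes outside it were in the table. Parvalbumin (Pvalb), the calcium buffer of fast fibres, was 10.2-fold higher in H4-TG, with a log2 signal of 10.20 against 6.85. Its probe lies on chromosome 15 at 78021535 to 78036781 in the authors' table, whose genome build is not stated. Several genes of the contractile apparatus were higher by 7-fold or more. Fast troponin T (Tnnt3) was 8.37-fold higher, skeletal actin (Acta1) 7.65-fold, nebulin (Neb) 7.54-fold, the fast myosin heavy chain Myh4 7.53-fold, actinin 3 (Actn3) 7.34-fold, Myh1 7.17-fold and the myosin-binding protein Mybpc2 7.06-fold. The calcium pump of the sarcoplasmic reticulum, Atp2a1, had a signal of 11.20 against 8.16, or 8.23-fold more. Muscle creatine kinase (Ckm) was 6.94-fold higher. Triadin (Trdn), of the calcium release complex, was 8.44-fold higher by its brightest probe, and its 7 probes ranged from 1.01 to 3.08 in log2 difference. The Z-disc protein myotilin (Myot) was 8.08-fold higher. The smallest differences on the list were 0.66 for Tcap and 0.99 for the slow myosin Myh7, both below the signal minimum. Of the 25 members, 22 were above it.

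The median difference over the 25 muscle genes was 2.55, which is 5.86-fold. Random lists of 25 named genes with matched mean signal had medians mostly between 0.67 and 0.89, and the muscle list lay above all of 10000 such lists. The authors' table holds only probes higher in H4-TG, so this ranks the list among higher genes.

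**Figure D1:**
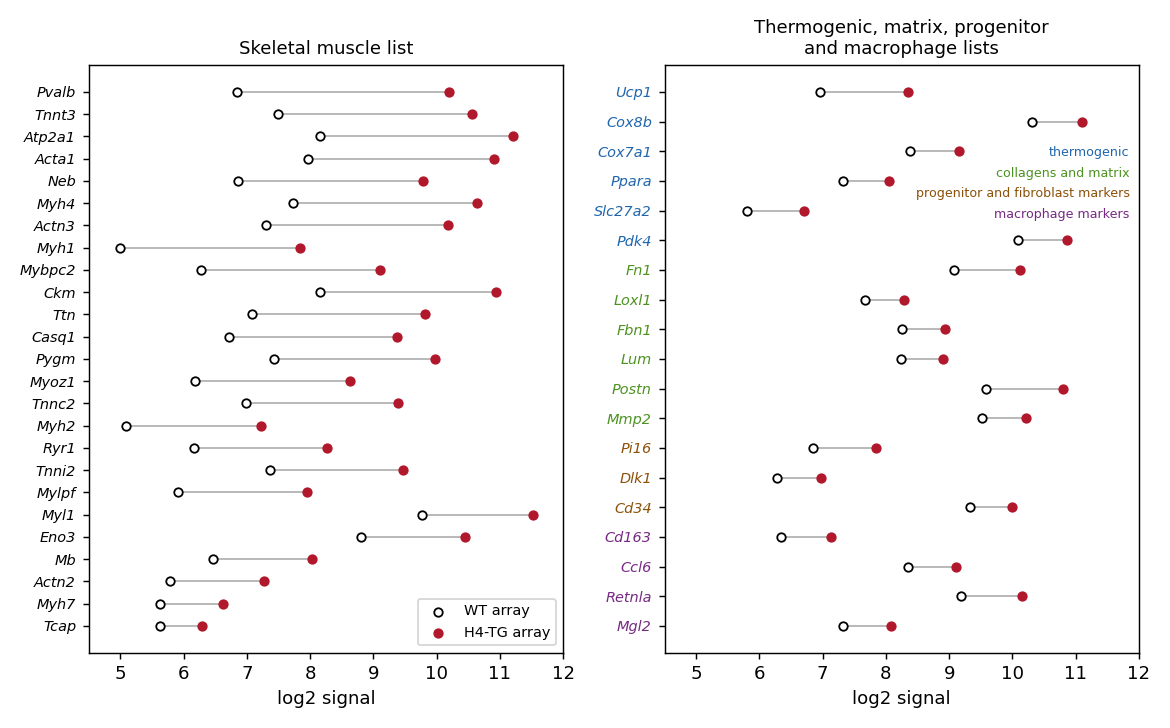
Log2 signal on the WT array (open circles) and the H4-TG array (filled circles) for the listed members of 5 gene lists, 1 array per genotype. The 25 muscle genes (left) differ by 0.66 to 3.35, and the thermogenic, matrix, progenitor and macrophage genes (right, gene names coloured by list) by 0.63 to 1.38.

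Ucp1, the uncoupling protein of brown and beige adipocytes, was 2.60-fold higher in H4-TG, with a log2 signal of 8.35 against 6.97. Its probe lies on chromosome 8 at 85814251 to 85822351 in the authors' table. Of the 34 genes of the thermogenic list, 6 were in that table and only Ucp1 reached 2-fold. The others were the cytochrome oxidase subunits Cox8b (1.73-fold) and Cox7a1 (1.72-fold), the pyruvate dehydrogenase kinase Pdk4 (1.71-fold), the fatty acid receptor Ppara (1.65-fold) and, below the signal minimum, the fatty acyl-CoA ligase Slc27a2 (1.88-fold). Cox8b, Cox7a1, Pdk4 and Ppara are expressed in muscle as well, and the muscle list was higher on the same array by a median log2 difference of 2.55. The median over the 6 was 0.79, at percentile 63.3 of random lists of named genes, all of them higher in H4-TG. The named genes drawn from include the muscle genes, so this rank depends on their differences too. It does not place the thermogenic list as a whole. Cidea, Prdm16, Ppargc1a and Dio2 were not in the table and have no value here.

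Extracellular matrix and fibroblast genes were also in the table. Of the 31 genes of the matrix list, 6 were listed, and 2 of them exceeded 2-fold: periostin (Postn, 2.32-fold, 10.80 against 9.58) and fibronectin (Fn1, 2.05-fold). Gelatinase A (Mmp2) was 1.62-fold and fibrillin 1 (Fbn1) 1.61-fold higher. The median over the 6 listed genes was 0.69, at percentile 24.6 of random lists of named genes, all of them higher in H4-TG. Members not listed have no value, so this rank does not place the matrix list as a whole. It depends on the muscle genes too, which are among the named genes drawn from. Of the 19 progenitor and fibroblast markers, 3 were listed: Pi16 (7.84 against 6.84), Dlk1 (1.61-fold) and Cd34 (1.58-fold). No collagen gene of the list was in the table. Skeletal muscle tissue also holds fibroblasts and matrix, and its markers were 5.86-fold higher by median. Whether muscle RNA contributed to the matrix and fibroblast differences was not tested.

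Of the 26 macrophage markers, 4 were listed, all under 2-fold: the resistin-like protein Retnla (1.94-fold), the haemoglobin scavenger receptor Cd163 (1.73-fold), the chemokine Ccl6 (1.68-fold) and the lectin Mgl2 (1.68-fold). Among neutrophil and mast cell markers 3 of 16 were listed, of which only the tryptase Tpsb2 (1.56-fold) was above the signal minimum. No member of the B cell, T and natural killer cell, lymph node, endothelial or erythroid lists was in the table. Of 14 smooth muscle markers only desmin (Des, 1.70-fold), which skeletal muscle also expresses, was listed. Epithelial and skin markers had 2 of 25 listed and nerve markers 1 of 16, all below the signal minimum.

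Among lipid and glucose genes, the lipolysis list had 3 of 23 listed: the lipase co-activator Abhd5 (1.74-fold), the lactate receptor Hcar1 (1.59-fold) and the kinase subunit Prkar2b (1.51-fold). Fatty acid oxidation had 2 of 22, Ehhadh (1.59-fold) and Acsl1 (1.52-fold, 12.55 against 11.95). White adipocyte genes had 2 of 30, angiotensinogen (Agt, 1.65-fold) and Zfp423 (1.51-fold); Adipoq, Lep, Fabp4 and Pparg were not listed. Glycolysis had 1 of 20, the lactate transporter Slc16a3 (1.58-fold). The creatine list had 1 of 11, muscle-type mitochondrial creatine kinase (Ckmt2, 3.11-fold, below the signal minimum). Muscle expresses Slc16a3 and Ckmt2 as well, and the muscle list was higher on the same array by a median log2 difference of 2.55. None of the 34 respiratory chain, 22 lipogenesis or 20 cholesterol synthesis genes was listed.

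Stress genes had 3 of 28 listed, namely Fosb (1.84-fold), Hspa1a (1.72-fold, with a near-identical copy in Hspa1b) and Egr2 (1.55-fold). Chac1 (1.87-fold) was the 1 listed gene of 22 in the ATF4 list, and Pdk4 and Zbtb16 (1.56-fold) were the 2 of 14 in the glucocorticoid list. No gene of the cell cycle, interferon, circadian, ribosomal protein, reference gene or sex check lists was in the table. The expansion of H4 was not known, so 21 genes it could stand for had been listed. Only the histamine receptor Hrh4 was in the table, at 4.57 against 3.58, below the signal minimum. Hdac4 was not, nor was any gene of the class IIa HDAC, SIK and MEF2 list, so no value checks the transgene.

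Across the array, 112 of the 17778 probes above the signal minimum were at least 2-fold higher in H4-TG and 166 at least 2-fold lower, so 40.3% of these were higher. That share was 44.3% after median centring (121 higher, 152 lower), 51.0% after quantile normalization and 50.0% after centring along signal level. The lowest identifiers of the array carry no gene name in the files, and whether they are control probes rather than genes is not given in the sources used here; without them 89 were higher and 71 lower. The higher side held 69 named genes, 22 of them on the muscle list. Further muscle genes among the 69 were not on that list, such as Trdn and Myot, given above. Other examples, chosen after their values were seen, were the myosin-binding protein Mybpc1 (4.51-fold), Cmya5 (4.39-fold), tropomyosin Tpm2 (4.21-fold), AMP deaminase Ampd1 (4.16-fold), Klhl41 (3.96-fold) and tropomodulin Tmod4 (3.85-fold). The rest of the 69 were not sorted into muscle and other genes, so 22 is not the number of muscle genes among them. On the lower side, the probes outside the lowest identifiers with the largest differences were 10429560 (5.51 against 8.10) and 10598085 (6.16 against 8.45), neither of which could be named.

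**Figure D2:**
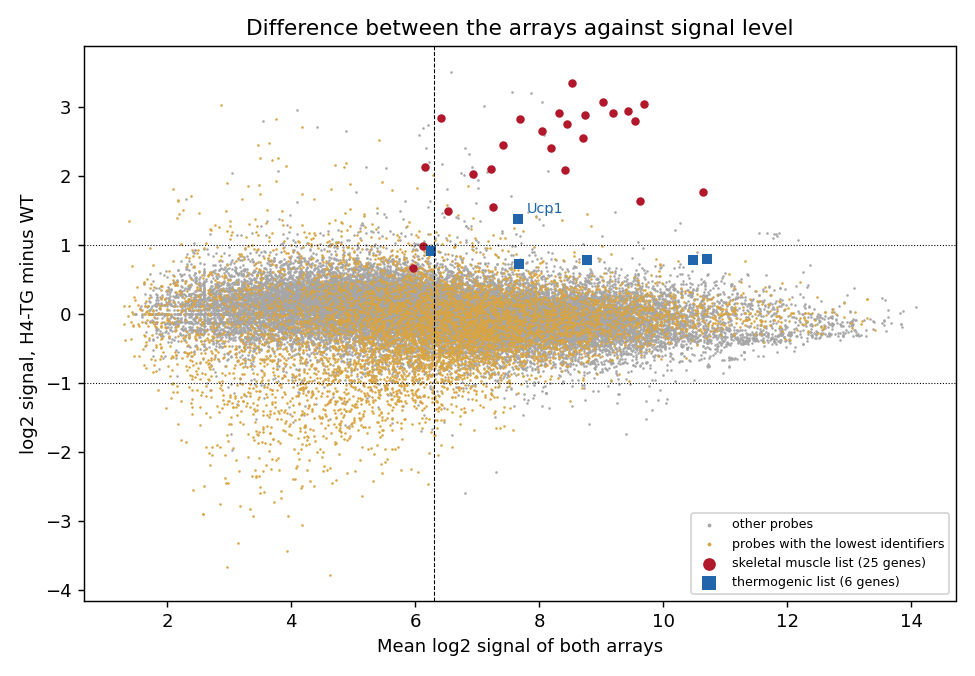
Difference in log2 signal (H4-TG minus WT) against the mean log2 signal of both arrays for 35556 probes, with dotted lines at 2-fold and a dashed line at the signal minimum of 6.31. The 25 muscle genes lie above the bulk of probes, Ucp1 lies at 1.38, and the probes with the lowest identifiers (ochre) spread downwards at low signal.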

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

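Median centring, quantile normalization and centring along signal level (the last chosen after seeing the data) kept the muscle median between 2.55 and 2.65 and Ucp1 between 1.38 and 1.48. Of the 42 named genes, 4 moved by over 0.1 under quantile normalization, 5 under centring along signal level and 2 with the mean over probes. All come from a table of higher probes, and median centring adds the same 0.03 to each, so the absence of reversals says nothing about stability. The muscle median was 2.45 with the mean over a gene's probes, which brings in dimmer Ttn probes, and 2.70 over members in the top 40% of probes. The thermogenic median was 0.89 after centring along signal level. Without matching on signal, the listed thermogenic genes stood at percentile 81.1 of random lists of named genes and the listed matrix genes at 36.2. Counts followed the thresholds by construction. Without a signal minimum 317 probes were higher, 844 lower, and 120 named genes higher; with the stricter minimum these were 72, 95 and 45; at 1.5-fold they were 410, 1117 and 244. Without the lowest identifiers, also chosen after seeing the data, 71 probes were at least 2-fold lower. The other offset before the logarithm was not run because the values are log2 already. No paired analysis was possible because each genotype has 1 array, and for the same reason no array could be left out.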

Other observations

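Among named genes outside the lists, chosen after their values were seen, a secreted Wnt modulator (Sfrp2, 2.23-fold), the matrix proteins Efemp1 (2.20-fold) and Pcolce2 (2.44-fold), and the stromal antigen Cd248 (1.85-fold) were higher in H4-TG. The imprinted RNA H19 was 2.37-fold, the paraoxonase Pon1 3.27-fold and the non-classical MHC gene H2-M9 4.10-fold higher. The cytochrome P450 gene Cyp2e1 (1.63-fold, 12.71 against 12.01), the amino acid transporter Slc7a10 (1.60-fold) and the insulin receptor substrate Irs1 (1.53-fold) were also in the table. Of 13 probes annotated to major urinary proteins (Mup), the 9 with a WT signal of 9 or more differed by 1.07 to 1.31. Those 9 probes each carry several Mup symbols, so the family members cannot be separated. The largest difference on the array above the signal minimum, 11.4-fold, was that of a probe annotated to both Mela and Kcnma1. Above the signal minimum, a further 6 unnamed probes outside the lowest identifiers were at least 2-fold higher, the largest, 10362422, by 9.30-fold. Its identifier, and that of the next, 10362434, lie close to the brightest Trdn probe, 10362420. Whether these 6 probes belong to genes named above is not given in the sources used here.

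The tests below were chosen after the data were seen, except that values under median centring and quantile normalization were planned. The first pattern is the skeletal muscle list. A scaling shift shared by all probes is argued against. Over the probes above the signal minimum the median difference was -0.09, with quartiles of -0.29 and 0.11. The muscle median was 2.55 as deposited, which was its lowest value over the scalings, and at most 2.65. A candidate explanation is more muscle RNA in the H4-TG pool, for instance from tissue taken with the fat in 1 or more of the 4 animals: 25 of 25 fixed members were in the table, and contractile, calcium-handling and metabolic muscle genes were higher together. On the WT array, Myl1 (9.76), Atp2a1 (8.16) and Ckm (8.15) were above the upper quartile of 7.92. Other listed muscle genes, such as Myh2 (5.10) and Tcap (5.63), were below the WT median of 6.34. The WT pool may thus have held some muscle RNA too, and a difference in its amount would need no transgene effect. Expression of muscle genes by fat cells of the transgenic mice stays open as well. It cannot be told apart from more muscle RNA, because genotype and dissection coincide with 1 array per genotype.

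The second pattern is the thermogenic list. Muscle RNA may contribute to Cox8b, Cox7a1, Pdk4 and Ppara, which muscle expresses. Ucp1 is not known as an abundant muscle transcript, and its lowest difference over the scalings was 1.38, but with no spread between replicates this decides nothing. More brown-like adipocytes would be a biological explanation. It is left open too: 0 of Cidea, Prdm16, Ppargc1a and Dio2 were in the authors' table, and a gene missing from that table has no value here. Outside the lowest identifiers, 1066 probes were at least 1.5-fold higher, and the authors' table held 849 of them. Absence from it makes a rise of that size less likely for these genes but does not exclude it.

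The third pattern is the excess of lower probes, which at 2-fold was not present without the lowest identifiers, where 71 probes were lower and 89 higher, or 50 and 99 after centring along signal level. With these probes kept, it was present after median centring (152 lower, 121 higher) and was not present after quantile normalization (127 lower, 132 higher) or centring along signal level (132 and 132). At 1.5-fold, above the signal minimum, the lowest identifiers are not enough, since without them 686 were lower and 296 higher; with no minimum, 1089 were lower and 1066 higher. Whether a technical shift along signal level lies behind the part above the minimum stays open: centring along it left 419 lower and 447 higher, but would remove a general shift of any origin. No biological explanation was tested for this pattern.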
